A study of Drosophila melanogaster with 30 samples.

How the data were processed

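RNA from whole Drosophila melanogaster embryos was sequenced in 30 samples. They form 5 genotypes at 2 collection times, with 3 biological replicates per genotype and time and more than 200 embryos per collection, per the labels. Libraries of embryonic stage 16 (St16) were read as single reads of 50 bp, and libraries of the late stage named for the air-filled trachea (AFT) as paired reads of 150 bp, with 30 to 50 M reads per sample, per the labels' protocols. The read layout therefore differs between the stages in the same way as the stage itself.

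The deposited values are in TPM, a unit in which the sum over transcripts is fixed in each library. Per the submitters' processing notes, kallisto 0.43.1 and genome build BDGP6 were used. How transcripts were summed to genes is not given in the sources used here. There is 1 table per stage, with 14040 genes at St16 and 14077 at AFT. Each table holds 1 TPM column per genotype, and these columns are the authors' means: multiplied by 3, 56.2% of the values between 10 and 100 TPM at St16 and 54.5% at AFT came within 0.02 of a whole number in the 4th decimal, against 19.9% to 28.0% for factors of 1, 2, 4 and 5. Values of single libraries were not used here. Each table also holds 4 lists of genes with log2 fold changes, made by the authors from the deposited TPM. These lists hold exactly the genes with a TPM ratio of 2 or more in either direction, a TPM of 1 or more in at least 1 of the groups compared and no value of 0. No gene was in only 1 of the lists and of the set this rule gives, so replicate error played no part in them.

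The design fixed before the data were examined was a limma fit across replicates. It could not be made with 1 mean per group. Every comparison below therefore has no replicate check, no test, no p-value and no SD. Differences are given as sizes only, and "higher" and "lower" describe the authors' means. TPM keeps no read depth, so the depth behind a single value is unknown and no counting interval can be given.

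Fold changes were computed as differences of log2(TPM + 1), which understates the change of genes of low TPM. A gene entered a comparison with a TPM of at least 1 in either group, and was counted as apart at 2-fold or more on that scale. For joint misexpression the non-additive value is the log2 level in col + lbe minus that in col, minus that in lbe, plus that in the control. The stage difference is the log2 fold change at AFT minus that at St16. Because each stage comes from its own table, levels set across stages are across tables.

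Named genes follow a rule fixed before the data were examined, without its conditions on p-values and replicates: per comparison and direction the 6 genes with the largest fold change among those with at least 5 TPM in 1 of the groups compared and a symbol other than a CG or CR number, and 4 per direction for the other contrasts. The misexpressed genes, Nplp1, FMRFa, dimm and w are always reported, with up to 4 members of a described list. A gene whose symbol begins with digits is given by its identifier, FBgn0052208. Other genes are said to be chosen after their values were seen.

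The 25 gene lists were fixed before the data were examined. For each list and comparison the median log2 fold change was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A median is called extreme at or above the 99.9 percentile or at or below the 0.1 percentile of the random lists, a limit chosen after the tables were found to hold no replicates. The percentile describes these means and is no test. Medians are given relative to the median of all genes in the comparison. The misexpressed genes were left out of every list other than their own.

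Near-identical gene copies share reads, so values of single Hsp70, Lys, Jon, Lcp65Ag and Cpr65Ax genes are uncertain. Reads from a UAS transgene cannot be told from those of the gene itself. In 5 gene names a spreadsheet had made dates, which were restored to Sep1, Sep2, Sep4, Sep5 and dec-1. Gene positions and identifiers come from the BDGP6.54 annotation, in which 12874 of the 14040 symbols at St16 were found. The tables hold no coordinates.

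Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, rescaling by the median ratio and quantile normalisation, and for overlaps the 200 genes of largest fold change, in place of the smallest p, and the counts without the misexpressed genes. After the data were seen, these were added: the plain TPM ratio with no pseudocount, a threshold of 3-fold, the median of the other 4 groups as the reference, counts without cuticle, gut and moulting-age genes, genes apart from all 4 other groups of a stage, and stage differences without genes listed at 0 in a whole table. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Simulated data for the col comparison at AFT held 9876 genes, of which only a small part was planted with a change. All 66 genes planted with a 4-fold change and 66 of 67 with a 3-fold change passed the 2-fold limit. Of 67 planted with a 1.5-fold change, 1 passed. The 3-fold and 4-fold changes lie above the limit by construction, so their recovery checks the computation only. It does not show how well the 2-fold rule finds changes in genes of low TPM.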

Results

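Transcript levels were measured by RNA sequencing in whole fruit fly embryos in which transcription factors were switched on throughout the nervous system. The elav-Gal4 driver, which is active in neurons, drove transgenes for collier (col, listed under its other name knot, kn), for ladybird early (lbe), for col and lbe together, or for apterous (ap) and eyes absent (eya) together. Embryos with the driver over a wild-type OregonR chromosome served as the control. Each of the 5 genotypes was collected at embryonic stage 16 (St16) and later, when the trachea fill with air (AFT), with 3 biological replicates per genotype and stage, 30 samples in all. The values used are the authors' means in TPM, a unit that scales transcript abundances to a fixed sum per library, with 1 value per gene, genotype and stage, so no difference below could be set against the spread between replicates. The TPM columns summed to between 996237 and 997034 at St16 and between 984625 and 991941 at AFT, and held 9598 to 9714 and 9739 to 9871 genes at 1 TPM or more. These sums are set by the unit and say nothing about sequencing depth, which is unknown for single values.

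The first comparison asked whether each misexpressed gene was higher where its transgene was driven. At St16, kn stood at 25.9 TPM in the control, 92.4 in col and 81.0 in col + lbe. The homeobox gene lbe was at 0.0633 TPM in the control, 61.2 in lbe and 68.2 in col + lbe. In ap + eya embryos, ap was at 92.8 TPM against 10.5 in the control, and eya at 88.8 against 11.2. At AFT, kn was at 12.4 TPM in the control, 43.4 in col and 104 in col + lbe, and lbe at 0.0488, 48.9 and 88.0 TPM in the control, lbe and col + lbe. The level of kn was lower in lbe at AFT, at 5.15 TPM (log2 fold change -1.12). In ap + eya at AFT, ap was at 29.8 TPM (log2 fold change 2.93) and eya at 25.7 (2.93). These levels include any reads from the transgenes. On BDGP6.54, kn (FBgn0001319) lies on 2R from 14772650 to 14807061, lbe (FBgn0011278) on 3R from 21441577 to 21446537, ap (FBgn0267978) on 2R from 5706202 to 5727525 and eya (FBgn0000320) on 2L from 6527447 to 6546976, all on the minus strand.

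The levels of ap and eya were also higher in col + lbe embryos, which carry transgenes for neither. At St16, ap was at 55.9 TPM (log2 fold change 2.30) and eya at 36.6 (1.63). At AFT, ap was at 31.9 TPM (3.03) and eya at 23.8 (2.83), close to their levels in ap + eya. In col alone ap was at 15.2 TPM at St16 and 4.67 at AFT, and in lbe alone at 11.8 and 3.41. The gene Nplp1 (FBgn0035092, 2R from 25032377 to 25040377, plus strand) encodes a neuropeptide precursor of a subset of ap neurons. At AFT it was at 42.0 TPM in the control, 81.9 in col, 70.9 in lbe, 1339.7 in col + lbe and 47.0 in ap + eya. The log2 fold change in col + lbe was 4.96, a TPM ratio of 31.9. At St16 Nplp1 was at 11.4 TPM in the control and 45.2 in col + lbe (1.90), and between 10.6 and 15.4 in the other misexpressions. The peptidergic regulator dimm (FBgn0023091, 2L from 21331756 to 21342155, plus strand) was at 0.981 TPM in the control and 3.51 in col + lbe at AFT (1.19), and at 1.99 and 4.56 at St16 (0.89). FMRFa, the neuropeptide gene of another ap neuron, was low at St16: 0.162 TPM in col + lbe at St16 against 0.251 in the control, and at AFT it was at 5.45 against 4.53. The eye pigment gene w was at 20.3 TPM in the control at St16 and between 9.71 and 12.6 in the misexpressions, and at 10.9 against 2.33 to 5.13 at AFT.

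**Figure D1:**
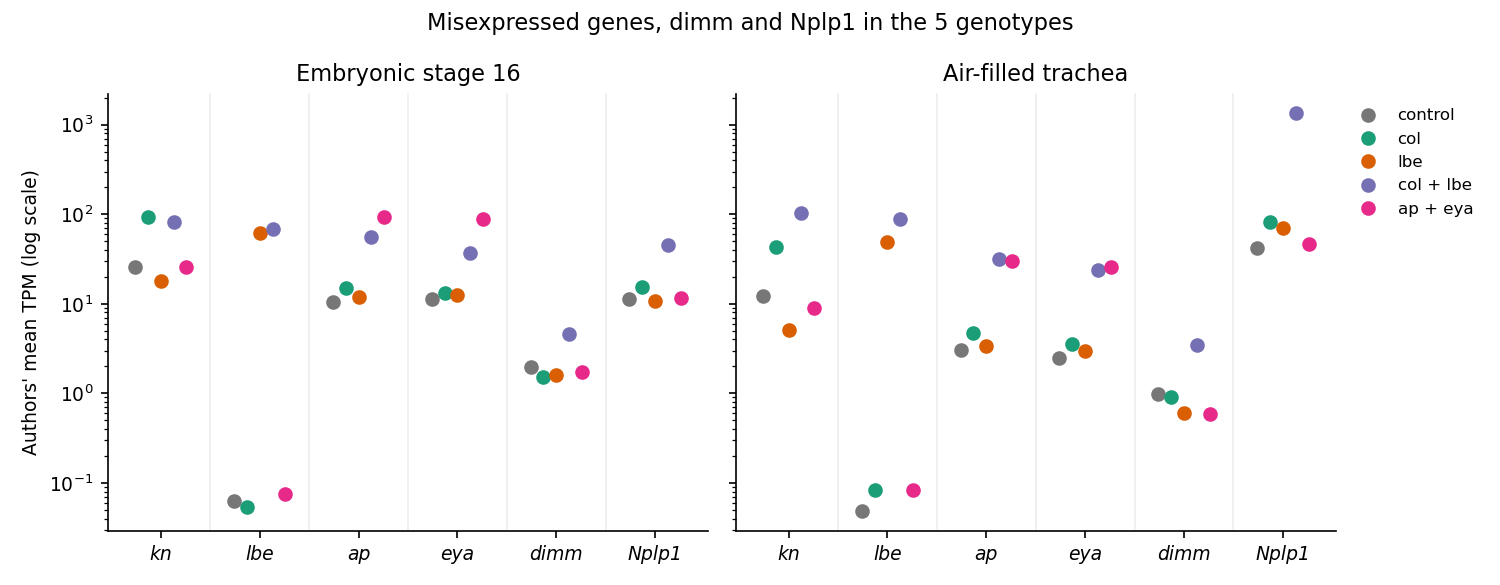
Authors' mean TPM (log scale) of kn, lbe, ap, eya, dimm and Nplp1 in the 5 genotypes at both stages; each point is 1 mean of 3 replicates, with no error bar because only means were used. In col + lbe, Nplp1 sits at 1339.7 TPM at AFT against 42.0 in the control, and ap and eya sit near their AFT levels in ap + eya.

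Counts of genes at least 2-fold apart from the control were smaller at St16 than at AFT. At St16, 28 genes were higher and 33 lower in col, 25 and 27 in lbe, 42 and 195 in col + lbe, and 42 and 116 in ap + eya, of 9799 to 9833 genes compared. At AFT, 191 were higher and 237 lower in col, 148 and 199 in lbe, 337 and 407 in col + lbe, and 185 and 260 in ap + eya, of 9984 to 10119 genes. All 4 comparisons of a stage use the same control mean, so anything peculiar to that mean enters each of them. With the median of the other 4 groups as the reference, the AFT totals came to 58 in col, 78 in lbe, 311 in col + lbe and 95 in ap + eya. More genes were then higher than lower in col (40 and 18), lbe (44 and 34) and col + lbe (209 and 102), and fewer in ap + eya (42 and 53). After rescaling by the median ratio, the median of all genes at AFT moved by 0.085 in col, 0.11 in lbe, -0.10 in col + lbe and 0.10 in ap + eya. Then 219 genes were higher and 196 lower in col, 178 and 159 in lbe, 294 and 469 in col + lbe, and 212 and 214 in ap + eya. The same rescaling at St16 gave 30 higher and 25 lower in col, 28 and 22 in lbe, 43 and 180 in col + lbe, and 41 and 110 in ap + eya.

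**Figure D2:**
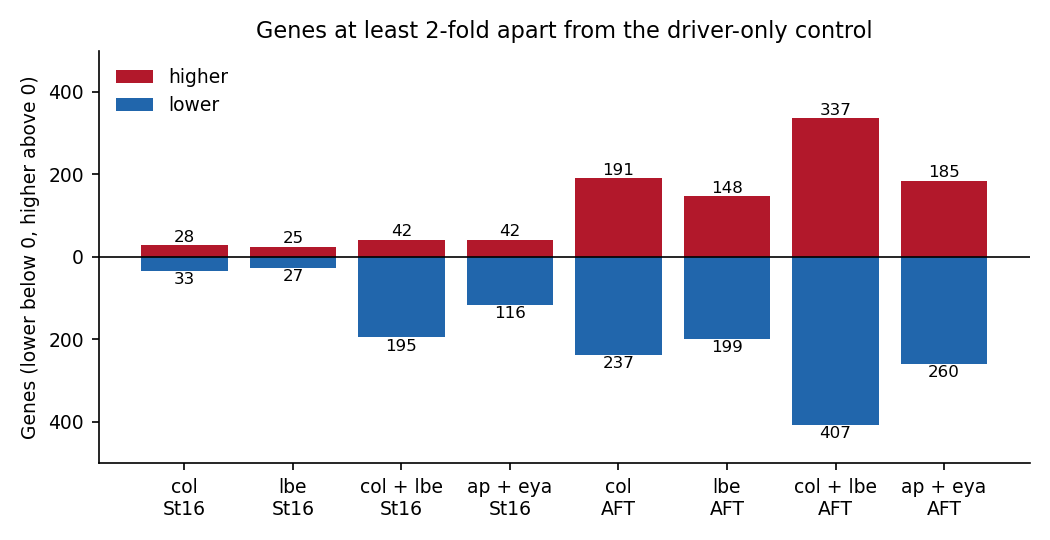
Number of genes at least 2-fold higher (above 0) or lower (below 0) than the driver-only control in each misexpression at each stage, from the authors' means. The bars run from 25 higher and 27 lower in lbe at St16 to 337 higher and 407 lower in col + lbe at AFT.

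With col alone at St16, the named genes of largest difference were of several kinds. The larval cuticle gene Lcp9 (log2 fold change 2.24), the immune-induced IM14 (1.97), the photolyase gene phr (1.82), the lysozyme gene LysX (1.41), gdl-ORF39 (1.33) and the stress gene TotF (1.33) were higher, with 5 genes known by CG or CR number among them in rank. Lower were the heat shock gene Hsp70Bc (-4.88), GILT3 (-2.55), the bHLH gene Fer2 (-1.36), Lcp65Ag3 (-1.23), Sid (-1.03) and the neuropeptide gene Pdf (-1.03), with 13 such numbered genes. Hsp70Bc is a near-identical copy, and the Hsp70 copies summed did not show this difference: they came to 631 TPM in the control and 490 to 669 in the misexpressions. Neurotransmitter synthesis and transport genes had a median of -0.18 relative to all genes over 22 members, none of them 2-fold apart. The beat and side families (-0.15), the Notch target genes of the E(spl) complex (-0.21) and the wing patterning genes that depend on ap (-0.15) also had extreme low medians. The total of 61 genes was 127 with a pseudocount of 0.1 and 18 with 5.

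At AFT in col, LysD (4.68), LysS (3.79), LysB (3.78), the chitinase gene Cht9 (3.32), TwdlO (3.29) and the protease gene Jon25Bii (3.08) led the higher genes, with 15 numbered genes among them. These named genes were at least 2-fold higher in all 4 misexpressions at AFT, so their differences were not particular to col. Osi6 (-3.88), Ipod (-3.79), FBgn0052208 (-3.66), TwdlD (-3.65), TwdlF (-3.59) and phu (-3.56) led the lower ones, with 6. Of 95 cuticle protein genes 37 were lower and 3 higher, and of 12 fat body and gut markers 7 were higher, such as betaTry at 316 TPM against 38.8. Of 14 heat shock genes 10 were higher, among them Hsp27 (1.84) and Hsp23 (1.38). The sensory neuron channel genes ppk (1.56) and ppk26 (1.46) were higher, as was Gr28b (1.27). Among the 38 neuropeptide genes Nplp4 was higher (2.47), while Pdf (-1.22), Gpa2 (-1.32) and Orcokinin (-1.12) were lower. The cuticle, gut and heat shock differences had extreme medians of -0.73, 1.43 and 1.17 relative to all genes.

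With lbe alone at St16, the bHLH gene Fer2 (-1.54), the homeobox genes Dbx (-1.19) and Hmx (-1.03) and the GABA transporter gene Gat (-1.02) were lower. Hsp70Bc (-3.81) and Lcp65Ag1 (-1.20) were lower too, with 13 numbered genes among them. The serpin gene Spn28Da (4.07), the forkhead gene fd59A (1.57), Gbp3 (1.42), the zinc transporter gene ZnT35C (1.14), Sirup (1.11) and the cytochrome gene Cyp4p2 (1.08) were higher, with 5 numbered genes. The dpr and DIP families of cell surface proteins had a median of -0.21 relative to all genes, with 23 of 26 members below 0 and none 2-fold apart. Neurotransmitter genes (-0.16) and neuropeptide genes (-0.13) also had extreme low medians. The total of 52 genes was 117 with a pseudocount of 0.1 and 18 with 5.

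At AFT in lbe, 5 of 38 neuropeptide genes were lower and 1, Nplp4 (1.53), higher. Hug (-3.28), Ilp2 (-1.96) and NPF (-1.02) were lower, as were Lk at 2.01 TPM against 11.1 and Gpa2, listed at 0 against 2.66, and the list had a median of -0.30 relative to all genes. The sensory list had a median of -0.45 over 11 members, with ppk (-1.55) and ppk26 (-1.29) lower, the opposite direction to col. Dbx (-1.39) and Fer2 (-1.25), followed here because of their St16 values, were lower again, and fd59A was higher (1.23). The higher genes were led by LysD (4.08), lcs (3.30), LysB (3.24), TwdlO (3.16), LysS (2.73) and Jon44E (2.63), with 14 numbered genes among them. All of these named genes but lcs were at least 2-fold higher in all 4 misexpressions at AFT. Besides Hug, the lower genes were led by FBgn0052208 (-3.77), Ccp84Ae (-3.05), phu (-2.99), TwdlD (-2.56) and Twdlbeta (-2.45), with 9. Of 94 cuticle genes 24 were lower and 3 higher, and of 12 fat body and gut markers 5 were higher. The wing patterning list (-0.34) and the neurotransmitter list (-0.24) had extreme low medians, but not with a pseudocount of 0.1. The total of 347 genes was 551 with a pseudocount of 0.1 and 189 with 5.

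With col + lbe at St16, 43 of 79 cuticle protein genes were lower and none higher, with a list median of -1.05 relative to all genes. Without the cuticle, gut and moulting-age genes, 151 lower genes remained of 195. Genes outside this list that were at least 4-fold higher at AFT than at St16 in the control had medians of -0.22 in col + lbe, -0.14 in ap + eya, -0.11 in lbe and -0.083 in col, where all genes had -0.047, -0.016, -0.065 and -0.080. These medians were below every random list except in col. The median of the cuticle list was below every random list in all 4, relative to all genes -0.76 in ap + eya, -0.21 in lbe and -0.20 in col. Lcp65Ag1 (-3.03), Lcp65Ag3 (-2.99), TwdlM (-2.97), Cpr65Ax2 (-2.70) and Cpr62Bc (-2.62) were the named examples besides Hsp70Bc (-5.04), with 13 numbered genes among them. Higher were IM14 (2.67), the homeobox gene Six4 (2.52), the amylase gene Amy-p (2.34), Nplp1 (1.90) and the homeobox gene slou (1.66), with 8 numbered genes, and Mst57Dc, which was listed at 0 in the control. The GABA genes Gad1 (-1.55) and Gat (-1.66) were lower, and neurotransmitter genes had a median of -0.29. Of 26 neuropeptide genes, Nplp1 and CCHa2 (1.54) were higher and Pdf (-1.46) and AstC (-1.06) lower, around a list median of -0.25. The 16 peptide processing and dense core vesicle genes had a median of 0.15, with 12 above 0 and none 2-fold apart. Glial (-0.19), muscle (-0.15), E(spl) (-0.30) and wing patterning (-0.28) lists had extreme low medians with no member 2-fold apart. The total of 237 genes was 431 with a pseudocount of 0.1 and 133 with 5.

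At AFT in col + lbe, of 16 peptide processing and dense core vesicle genes 4 were higher and none lower: the amidating enzyme gene Pal2 was at 103 TPM against 32.9 (1.62), the convertase gene amon at 47.7 against 20.2 (1.20), the carboxypeptidase gene svr at 72.4 against 34.0 (1.07) and IA-2 at 114 against 45.3 (1.31). The list median of 0.21 relative to all genes was not extreme. Neuropeptide genes were apart in both directions, 5 higher and 6 lower of 38, around a median of -0.20 relative to all genes that was extreme, but not after median-ratio rescaling. Nplp1 (4.96), Nplp4 (3.52), Proc (1.81), CCHa2 (1.28) and Dh44 (1.08) were higher, and Hug (-2.30), Ilp2 (-1.97), Lk (-1.82), Gpa2 (-1.70), NPF (-1.54) and Pdf (-1.43) lower. Among neurotransmitter genes, Hdc for histamine (1.82) and Trh for serotonin (1.51) were higher, and Gat (-1.43), Ddc (-1.22) and Gad1 (-1.19) lower.

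Other leading genes in col + lbe at AFT were lcs (5.91, 512 TPM against 7.51), LysD (5.23), LysS (4.89), TwdlO (4.58) and LysB (4.31), with 9 numbered genes among the higher. All of these named genes but lcs were at least 2-fold higher in all 4 misexpressions at AFT. Cpr65Ea (-3.86), Osi6 (-3.86), FBgn0052208 (-3.82), TwdlD (-3.62), TwdlF (-3.59) and TwdlC (-3.54) led the lower genes, with 4 numbered genes. Six4 was again higher at 21.9 TPM against 0.505 (3.93), and slou at 37.1 against 4.25 (2.86). Of 96 cuticle genes 50 were lower and 3 higher, and of 12 fat body and gut markers 8 were higher. All 5 antimicrobial peptide genes compared were above 0, and 4 of them 2-fold higher, including AttB (3.55) and Drs at 92.4 TPM against 11.0 (2.96), while IM1, IM2 and Mtk were listed at 0 in every AFT column. Of 12 heat shock genes 3 were lower, with a list median of -0.73. Among retinal determination and photoreceptor genes Arr1 (-2.95), Rh5 (-1.88), Arr2 (-1.29) and ey (-1.29) were lower, and the list median was not extreme. The total of 744 genes was 459 with a pseudocount of 5.

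With ap + eya at St16, cuticle genes were lower as well, 35 of 79 with none higher and a list median of -0.76 relative to all genes. Lcp65Ag1 (-2.90), Cpr65Ax2 (-2.87), Cpr65Ax1 (-2.54) and Lcp65Ag3 (-2.51) were the named examples besides Hsp70Bc (-4.60) and GILT3 (-2.67), with 4 numbered genes among them. phr (2.19), TotF (2.07), the antimicrobial gene Anp (1.87), Gbp3 (1.67), Cyp4p2 (1.56) and Prx2540-1 (1.43) were higher, with 8 numbered genes. The neuropeptide gene Dh44 was higher (1.24) and Pdf lower (-1.14). No axon guidance or wiring gene was 2-fold apart in any of the 8 comparisons, but in ap + eya at St16 this list had an extreme median of 0.18, with 46 of 59 members above 0. Its members included Ten-a (0.55), kirre (0.54), kek1 (0.53) and CadN (0.50), named after their values were seen. The pan-neuronal list (0.25, 16 of 20 above 0) and the neuroblast and cell cycle list (0.17, 22 of 24 above 0) were extreme in the same comparison. In the control, across tables, the axon guidance and the neuroblast lists were lower at AFT than at St16, with medians of -1.12 and -1.75, while the pan-neuronal list was higher (0.33). The total of 158 genes was 246 with a pseudocount of 0.1 and 79 with 5.

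At AFT in ap + eya, 5 of 38 neuropeptide genes were lower: Pdf at 1.77 TPM against 14.3 (-2.47), Hug (-1.65), Dsk (-1.40), Orcokinin (-1.34) and Trissin (-1.19). Nplp4 was higher (2.10), and Nplp1 was at 47.0 TPM against 42.0 (0.16). LysD (4.68), TwdlO (3.98), LysB (3.66), LysS (3.59), Jon44E (3.24) and Amyrel (2.84) led the higher genes, with 11 numbered genes among them. These named genes were at least 2-fold higher in all 4 misexpressions at AFT. TwdlD (-4.41), Osi6 (-3.83), FBgn0052208 (-3.73), TwdlF (-3.61), Cpr65Ea (-3.56) and Ipod (-3.38) led the lower ones, with 7. Of 13 heat shock genes 7 were higher, including Hsp27 (2.06), and of 95 cuticle genes 35 were lower and 2 higher. The GABA receptor gene Rdl was higher (1.05). Retinal and photoreceptor genes (-0.33) and tracheal and epidermal matrix genes (-0.36) had extreme low medians, with Rh5 (-1.76) and Arr1 (-1.36) lower in the former and Cht5 (-1.02) and Ddc (-1.21) in the latter. The total of 445 genes was 255 with a pseudocount of 5.

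**Figure D3:**
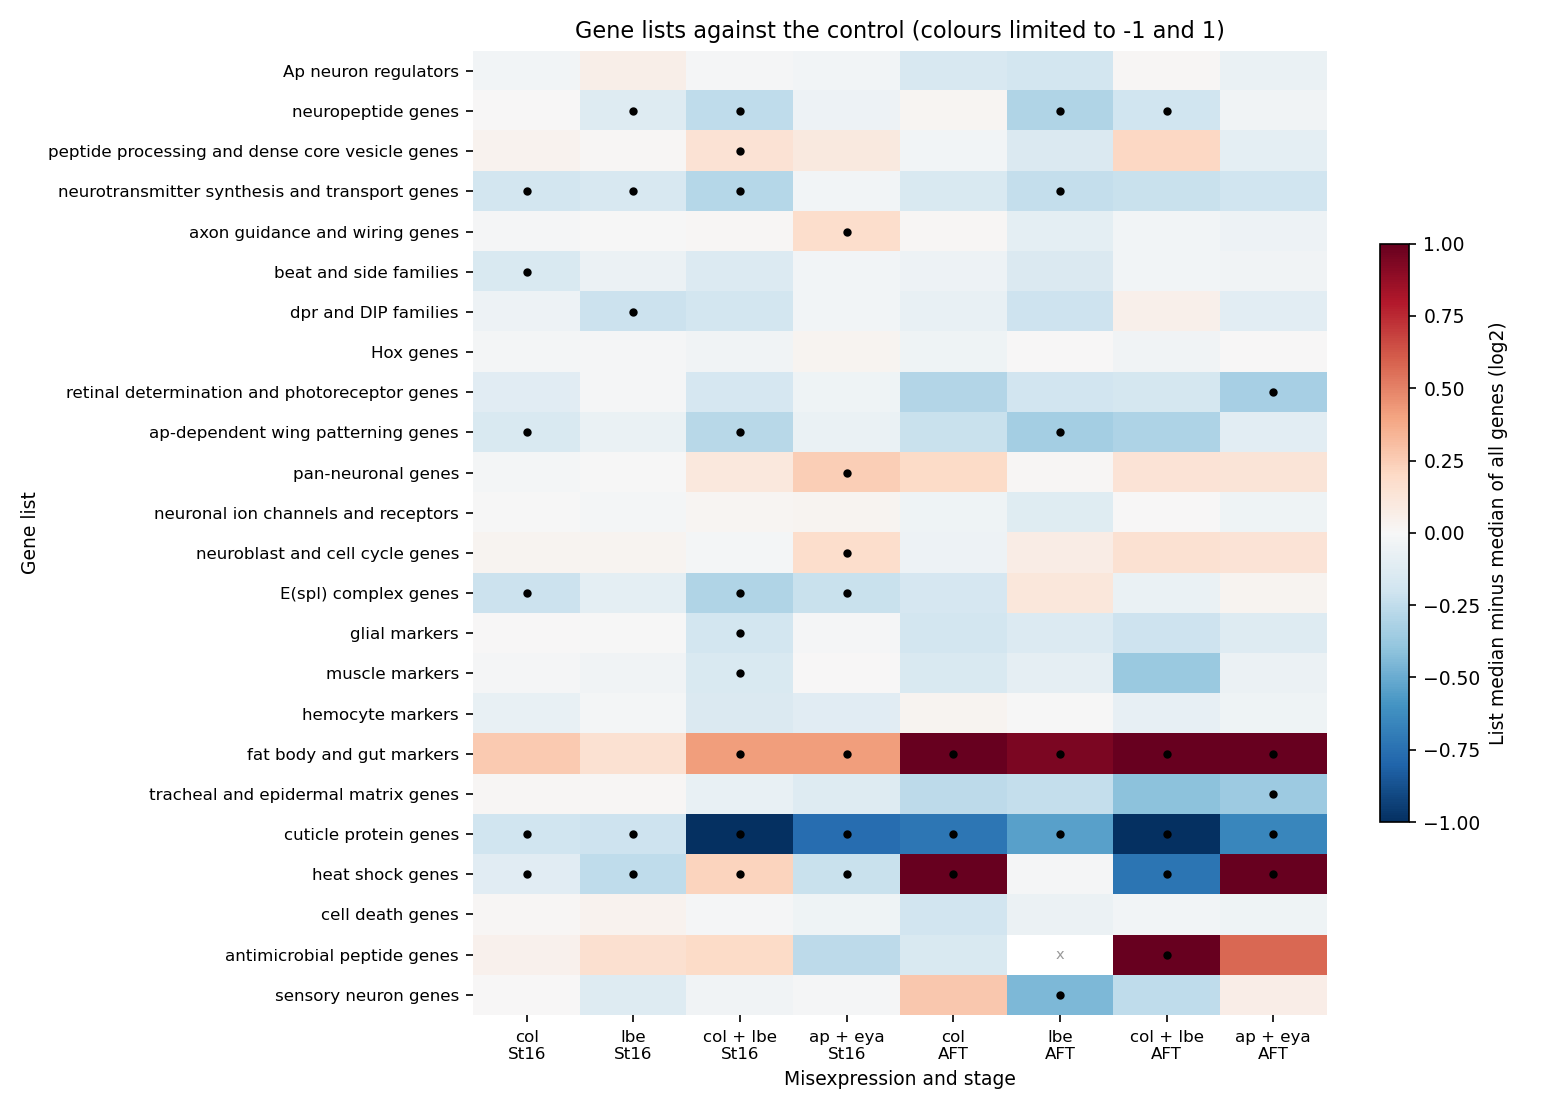
Median log2 fold change of each of 24 gene lists relative to the median of all genes, for the 4 misexpressions at both stages; dots mark medians at or beyond the 0.1 or 99.9 percentile of random lists matched on expression, and x marks a list with under 3 genes. Cuticle protein genes were below 0 in all 8 comparisons, from -0.20 in col at St16 to -1.21 in col + lbe at AFT.

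Of 191 medians of lists other than the misexpressed genes, 14 were extreme on the high side and 33 on the low side. The lists of ap neuron regulators, Hox genes, neuronal ion channels and receptors, hemocyte markers and cell death genes were extreme in none of the 8 comparisons, with relative medians from -0.19 to 0.06. At St16, fat body and gut markers were extreme in col + lbe (0.41, 5 of 7 above 0) and ap + eya (0.42, 3 of 5), the latter not with a pseudocount of 0.1. Heat shock genes were extreme in col (-0.12), lbe (-0.25), col + lbe (0.22) and ap + eya (-0.22), where Hsp70Bc alone was 2-fold apart. E(spl) genes were also extreme in ap + eya (-0.22). Among the ap neuron regulators, dimm in col + lbe at AFT was the only member 2-fold apart. Cell death genes 2-fold apart were grim in lbe (1.05) and col + lbe (1.41) and skl in col + lbe (1.58), all at AFT. In the list of the misexpressed genes themselves, all 4 were higher in col + lbe at both stages.

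The question of whether the joint response equals the sum of the single responses was put to col + lbe. On the log2 scale ap, eya, Nplp1 and dimm exceeded the sum of their single differences by 1.66, 1.25, 1.58 and 1.34 at St16 and by 2.40, 2.27, 3.27 and 1.55 at AFT. For kn the value was 2.37 at AFT. There kn was at 104 TPM in col + lbe against 43.4 in col, and lbe at 88.0 against 48.9 in lbe. The values above the sum at AFT therefore do not separate the pairing of col and lbe from these higher levels. At St16 kn was at 81.0 TPM against 92.4, and lbe at 68.2 against 61.2. At St16, 41 genes were at least 2-fold above and 108 below the sum, and at AFT 633 above and 223 below. The named genes above it were Hsp70Bc (3.65), GILT3 (2.47), dikar (1.69) and Six4 (1.63) at St16, and the antimicrobial gene Drs (4.16), phu (4.08), IM23 (3.75) and FBgn0052208 (3.62) at AFT, with 2 numbered genes among them at each stage. Below it were Spn28Da (-4.07), gdl-ORF39 (-2.51), Cpr65Ax2 (-2.14) and Sirup (-2.06) at St16, with 4 numbered genes, and LysD (-3.53), GstD5 (-3.02), Cyp6a2 (-2.80) and Hsp70Bbb (-2.74) at AFT, with 12. A gene that stands apart in the control alone also comes out as non-additive, because the control enters the sum. Rescaling by the median ratio moved the median of all genes at AFT by -0.29 and turned the split to 238 above and 426 below.

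**Figure D4:**
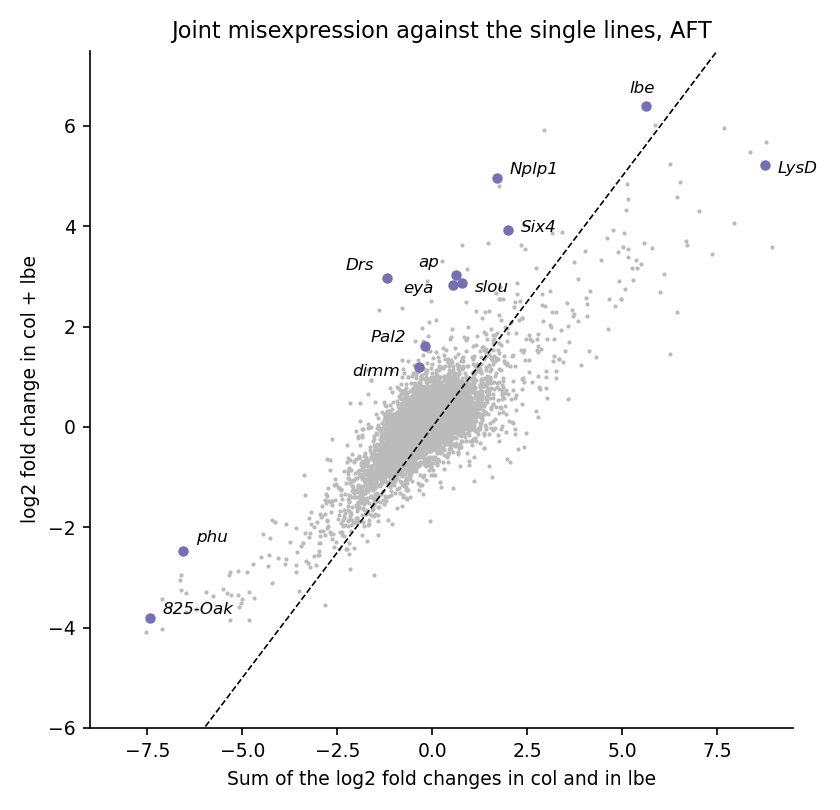
Log2 fold change in col + lbe (vertical) against the sum of the log2 fold changes in col and in lbe (horizontal) at AFT, each point a gene and the dashed line equality. Nplp1, ap, eya and dimm lie above the line, by 3.27, 2.40, 2.27 and 1.55, and LysD lies below it (-3.53).

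The difference between the stages was taken as the fold change at AFT minus that at St16. It was at least 2-fold up in 222 genes and down in 203 for col, 174 and 175 for lbe, 470 and 259 for col + lbe, and 208 and 189 for ap + eya. With the plain ratio it was up in 142 genes and down in 236 for col, 128 and 240 for lbe, 472 and 276 for col + lbe, and 153 and 238 for ap + eya. Among the named genes LysD was at 4.50 in col, 3.99 in lbe, 5.19 in col + lbe and 4.46 in ap + eya, and Osi6 at -3.87 in col, -3.79 in col + lbe and -3.85 in ap + eya. In col, LysS (4.13), LysB (3.89) and Hsp70Bc (3.70) followed, with FBgn0052208 (-3.75), Ipod (-3.73) and TwdlF (-3.58) at the other end. For lbe they were lcs (3.39), TwdlO (3.16) and LysB (3.15), with Spn28Da (-4.08), FBgn0052208 (-3.57), phu (-3.00) and Hug (-2.96). In col + lbe, lcs (5.85), LysS (4.97) and TwdlO (4.55) stood against Osi15 (-3.13), Osi20 (-3.09) and Cyp304a1 (-3.08), and in ap + eya TwdlO (3.92), LysB (3.78) and LysS (3.77) against TwdlF (-3.56), Osi15 (-3.21) and TwdlD (-3.20). Stage and read layout differ together here. For col + lbe, rescaling by the median ratio moved the median of all genes by -0.14 and gave 374 up and 332 down.

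The overlap of the responses was set against that of groups that share only a control. At AFT, the fold changes of different misexpressions correlated across genes with r between 0.71 and 0.88, where simulated unrelated groups with 1 shared control gave 0.50, and covariances were 0.177 to 0.250 against 0.0753 in the simulation. The simulated spread comes from differences between the misexpression means, and genes are not independent replicates. At St16, r was 0.51 to 0.68 and the covariance 0.0269 to 0.0750 against 0.0348 simulated, so that some pairs did not exceed it. In col + lbe and ap + eya at St16, 117 genes were apart in the same direction, 103 of them lower. This was 74.1% of the smaller set of 158 genes, where the other pairs at St16 shared 50.0% to 73.8% and the pairs at AFT 71.5% to 79.4%. Simulated groups with 1 shared control shared 39 genes at St16 and 82 at AFT. Several pairs at St16 did not exceed this, such as col and lbe with 11 genes higher and 15 lower in both. The simulated spread includes any effects of the transgenes, and for this pair the simulated covariance of 0.0348 exceeded the 0.0269 found. The simulated count may therefore be too high for this pair, and a common response is neither shown nor excluded. At AFT every pair exceeded the simulated count, with 140 to 202 shared lower genes alone. The simulated control had the same spread as the other groups, so a control mean that is itself apart would also exceed it. Across genes at AFT, the control correlated with the misexpressions at r of 0.954 to 0.977, and these with each other at 0.978 to 0.993. The excess over the simulation therefore does not show a common response. Among the 200 genes of largest fold change in each, pairs shared 82 to 124 at St16 and 127 to 144 at AFT, counts set against no simulated value here. Across the stages, which share no control, the same genotype gave r of 0.27 in col, 0.30 in lbe, 0.47 in col + lbe and 0.43 in ap + eya, and different genotypes 0.18 to 0.44. In all 4 misexpressions together, 6 genes were higher and 13 lower at St16, and 82 and 119 at AFT. In the control, across tables, the 82 genes were higher at AFT than at St16 by a median of 3.04 on the log2 scale, and the 119 had a median of -0.034. Of these 7 were lower at both stages, against 0.138 by chance: Hsp70Bc, CG13060, CG13239, CG13674, CG14095, CG32214 and CG33460, named after their values were seen.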

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

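No paired analysis was possible because the tables hold one mean per group. Settings chosen before the data were examined that need replicates or transcripts were not run: the fit of the compared groups alone, no trend, array weights, the robust fit, an adjusted p with a 2-fold limit, leaving out each replicate, a replicate block, the estimated correlation, fry and unsummed transcripts. The plain ratio, the 3-fold threshold, the reference from the other 4 groups and the counts without age-related genes or genes at 0 were chosen after the data were seen. All 14 counts stayed within 1.5 times their value with no filter, with median-ratio rescaling, with quantile normalisation and without the 188 cuticle, gut and moulting-age genes, though under both rescalings the split into higher and lower turned for col and lbe at both stages, for the stage difference of lbe and for the non-additive genes at AFT, and came near even for ap + eya at AFT and the stage difference of col + lbe. The split turned as well for the stage differences of col and ap + eya with a pseudocount of 0.1 and with the plain ratio, and for that of lbe with a pseudocount of 5, the 3-fold threshold and without genes at 0. It turned for col at AFT and lbe at both stages with a pseudocount of 5 and the 3-fold threshold, for col at St16 with a pseudocount of 5, and against the median of the other 4 groups for col and lbe at both stages and col + lbe at AFT. The 4 stage counts also stayed within it without genes at 0 in a whole table. No direction of a key gene at least 2-fold apart reversed. Of 191 list medians, 189 kept their side of the extreme limits under median-ratio rescaling and 187 with a pseudocount of 0.1. The neuropeptide list of col + lbe at AFT was no longer extreme under either, and with 0.1 nor were the neurotransmitter and wing patterning lists of lbe at AFT and the fat body and gut markers of ap + eya at St16; the antimicrobial list of ap + eya at AFT became extreme after rescaling. Of 12 overlaps between pairs, all stayed within 1.5 times their value without the misexpressed genes, and 1 did with the 200 genes of largest fold change. What depth limits is unknown, since TPM keeps no counts.

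Total counts beyond that range, for col, lbe, col + lbe and ap + eya in this order, were as follows. With a pseudocount of 5 they were 18, 18, 133 and 79 at St16, 268, 189, 459 and 255 at AFT, and 242, 175, 399 and 217 for the stage difference, with 48 and 348 non-additive genes at St16 and AFT. With 0.1 they were 127, 117, 431 and 246 at St16, 551 for lbe at AFT, and 696, 649, 1186 and 682 for the stage difference, with 284 and 1342 non-additive genes. With the plain ratio they were 136, 125, 458 and 265 at St16 and 591 for lbe at AFT, with 313 and 1395 non-additive genes. With the 3-fold threshold they were 17, 11, 118 and 65 at St16, 167, 125, 322 and 170 at AFT, and 162, 122, 276 and 157 for the stage difference, with 30 and 200 non-additive genes. A filter of 5 TPM gave 39 for col and 32 for lbe at St16. Against the median of the other 4 groups the counts were 28 for col, 27 for lbe and 81 for ap + eya at St16, and 58, 78, 311 and 95 at AFT. A larger pseudocount, a higher filter and a higher threshold each lower a count by construction; the cause of the fall against the other groups was not tested here, and the control is weighed under the other observations.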

Other observations

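All tests of explanations in this part were chosen after the results were seen, and the criteria for the tests of embryo age were tightened after their values had been seen. Genes of other processes also stood apart in ways not described so far, and all genes in this paragraph were chosen after their values were seen. The metallothionein gene MtnA was at 3227 TPM in the St16 control and between 6715 and 7847 in the misexpressions, and the zinc transporter gene ZnT35C was at 37.6 TPM in that control and between 80.3 and 95.7 in the misexpressions. The receptor ligand gene jeb was higher in all 4 misexpressions at AFT, from 1.03 in lbe to 1.44 in col + lbe. The dopamine and cuticle enzyme gene Ddc was lower in all 4 at AFT, from -1.21 in ap + eya to -1.50 in lbe. In col + lbe at AFT, 94 genes stood at least 2-fold above and 15 below every other group, against 8 and 0 in col, 4 and 3 in lbe and 8 and 6 in ap + eya. The control itself stood at least 2-fold above every other group in 119 genes and below in 82. By construction these are the genes already given as lower and higher in all 4 misexpressions at AFT, not a further result.

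The tables of the stages differ in their genes at 0. At AFT 41 genes were listed at 0 in all 5 columns although they reached 10 TPM or more at St16, and 4 genes were the other way round. Among the 41 were the ribosomal protein genes RpL41, at 42258 TPM in the St16 control, and RpL39, at 18627, as well as MtnA and the antimicrobial genes IM1, IM2 and Mtk. The longest annotated transcripts of 37 of them had a median of 992 nt, against 1951 nt for genes at 10 TPM or more in both tables. Ribosomal proteins are made in all growing cells, so a value of 0 in the AFT table is no evidence that a gene was silent. The authors' handling of such genes is not given in the sources used here, and no explanation was tested.

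In col + lbe, Nplp1, ap, eya and dimm were higher than in the control and either single line. If ap + eya embryos had been mixed into the collection, Nplp1 at AFT could not exceed its level in that line, but it was 28.5 times that level. This argues against mixing as the source of Nplp1. The levels of ap and eya were 1.07 and 0.93 times those in ap + eya at AFT, and 0.60 and 0.41 times at St16. Nplp1 cannot test mixing for them. At AFT, such levels from mixing would need nearly all embryos to be ap + eya ones. Yet lbe and kn were at 88.0 and 104 TPM in col + lbe there, against 0.0838 and 8.98 in ap + eya. This argues against mixing as the whole source of ap and eya at AFT. Mixing in part, and at St16, stays open for them. An older collection would raise other late neuropeptide genes alike, yet the median log2 fold change of the 25 others was -0.046, and ap and eya are lower at AFT than at St16 in the control. After median-ratio rescaling Nplp1 was still 4.85 log2 units higher, which argues against scaling. A response to col and lbe together is a candidate explanation named by the design, as a hypothesis without replicate values, and how much of the ap and eya level it accounts for was not tested. At AFT it cannot be told from a response to the higher levels there of kn (104 TPM against 43.4 in col) and lbe (88.0 against 48.9 in lbe). At St16 kn was at 81.0 TPM against 92.4 in col, and lbe at 68.2 against 61.2 in lbe. Yet ap, eya, Nplp1 and dimm exceeded the sum of their single differences there by 1.66, 1.25, 1.58 and 1.34. With no replicate check, this argues against a higher level of kn as their source at St16, while lbe was slightly higher.

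At AFT, 82 genes were higher and 119 lower in all 4 misexpressions, among them digestive and cuticle genes. If the control embryos were younger, the shared higher genes would be ones that increase with age, and in the control they were 3.04 log2 units higher at AFT than at St16 in the median, with 77 of 82 above 0; this is consistent with a younger control, from tables normalised separately. The shared lower genes went both ways, 59 above and 60 below 0 around a median of -0.034 where all genes had -0.29. They were picked by a high control mean at AFT, which also enters this change and biases it upward. Their median therefore cannot decide, and their part stays open. Under the first criteria this median would have counted for a younger control. The Osi genes, 6 of them among these, summed to 21969 TPM in the control at St16, 70.4 at AFT and 7.61 to 24.4 in the misexpressions at AFT, as with a younger control. The Twdl genes rose with stage instead, with 3690, 10515 and 3632 to 4944 TPM in the same order, and the Cpr genes with 2863, 22732.5 and 13840 to 23537. Times between the stages were not sampled, so these families do not decide it. A stock difference acting alike at both stages is argued against as the whole cause, since 13.0% of those with a TPM of 1 or more at St16 (17 of 131) were 1.5-fold apart the same way in all 4 there, and the rest of the shared genes could not be tested. A stock difference in part stays open: w was lower in all 4 at both stages, by -0.65 to -0.99 at St16 and -0.96 to -1.84 at AFT on the log2 scale. The control held the driver over an OregonR chromosome, and the w values say nothing about the other shared genes. Chance acting gene by gene in the control is argued against for the cuticle list, of which 68 of 94 genes in lbe and more in the others lay below the median of all genes. The fat body and gut list, also fixed beforehand, argues against it for its genes: 11 of 12 were above 0 in each comparison, with 5 to 8 of them 2-fold higher and none lower. Of the 82 shared higher genes, 77 were above 0 from St16 to AFT in the control, against 4093 of 10208 genes in all. Their low control mean at AFT pushes this number down, so it argues against chance for them as a set. Of 111 shared genes outside the cuticle list with 1 TPM or more at St16, 7 recurred there, against another control. These 7 were lower at both stages, where 0.138 were expected by chance. For the other shared lower genes outside the cuticle list chance stays open. Another difference of the whole control collection or an effect common to all 4 transgenes remains open and untested.

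At St16, cuticle protein genes were lower in col + lbe and ap + eya. Scaling is argued against: after median-ratio rescaling their median log2 fold change was -0.76 in ap + eya and -1.05 in col + lbe, and so is a lower output of all epidermal genes alike, since 16 of 17 tracheal and epidermal matrix genes lay above the cuticle median in each, with medians of -0.13 and -0.073 relative to all genes. Younger embryos in both collections may contribute, since genes outside the list that are at least 4-fold higher at AFT in the control had a median of -0.22 in col + lbe and -0.14 in ap + eya, and, with a smaller cuticle difference, -0.11 in lbe, but -0.083 in col, near the -0.080 of all genes, although the cuticle list was about as low in col as in lbe. Genes at least 4-fold lower at AFT were not higher, however, with medians of -0.039 and -0.025. They were picked by the St16 control mean that also enters these fold changes, which biases them downward, so this weighs little. Of the lists lower at AFT, the neuroblast and axon guidance genes were higher in ap + eya (0.17 and 0.18 relative to all genes) but not in col + lbe (-0.019 and 0.0081). The E(spl) list, lower still at AFT (median -2.10), was lower in ap + eya (-0.22) and col + lbe (-0.30). The wing patterning list was lower as well (-0.067 and -0.28), and the Hox list was near 0 (0.025 and -0.037). The gut list, higher at AFT, was higher in both (0.42 and 0.41, over 5 and 7 members). Age therefore stays open, and under the first criteria this would have counted for younger embryos. The lower genes were not limited to the cuticle list. Without the cuticle, gut and moulting-age genes, 151 of 195 remained in col + lbe and 81 of 116 in ap + eya. A response of the cuticle genes to these transgenes is not excluded and was not tested.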
